A study of Mus musculus with 12 samples.

How the data were processed

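Poly(A)-selected, strand-specific RNA sequencing libraries were made from CD4 T cells sorted from the spleens of C57BL/6 mice. Cells positive for CXCR5 and PD-1 are called T follicular helper (TFH) cells here, and cells negative for both are called non-TFH cells. The mice carried floxed Ets1 alleles without a Cre transgene (WT) or with CD4-cre, which deletes the floxed segment in T cells (labelled knockout, KO). The 12 libraries formed 4 groups of 3: WT non-TFH, KO non-TFH, WT TFH and KO TFH. The labels do not say whether replicates came from separate mice, so that p-values measure the spread between these samples, which may be technical.

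The authors' deposited values are FPKM (fragments mapped to a gene, divided by transcript length and library depth) per gene, in 1 Cufflinks gene tracking table per library. The submitters' processing notes name FastQC, cutadapt, TopHat2, TopHat, Bowtie2, Bowtie, Cufflinks and Cuffdiff and the genome build mm10. Their versions, order and settings are not given in the sources used here. Each table listed annotated genes beside unnamed assembled loci, so each library was quantified on its own. The tables hold no counts. A depth of 11.9 to 15.5 M fragments per library was estimated from FPKM and its confidence bounds at unnamed loci longer than 1500 bp. This is an estimate, and no counting intervals were drawn from it.

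Cufflinks had joined overlapping genes into a single entry in some libraries and not in others. A symbol was used as a feature of its own where it had its own entry in at least 2 libraries of every group (22451 features), and other symbols that shared an entry were summed into 796 joint features. Of the 23247 features, 21433 had a value in all 12 libraries, and a missing value was left missing. WT non-TFH replicate 1 lacked most genes of chromosomes X and Y. It alone had no value for 830 features, and Cxcr3, Sh2d1a and Tyrobp have n = 2 in that group. Lyz1 and Lyz2 have n = 2 in WT TFH cells. Unnamed loci and genes with symbols turned into dates (24 features) entered no named result. Some genes were listed at exactly 0 in some libraries and at high values in others. The tables do not show whether such a 0 is a measurement, and no fold is given against a group listed at 0.

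FPKM values were scaled between libraries by the median ratio over the 7167 features at 1 FPKM or more in every library (factors 0.857 to 1.14). Levels are scaled FPKM unless stated. Without this scaling the median gene differed between TFH and non-TFH cells by 0.37 log2 in WT and 0.27 in KO mice, so changes are relative to that median. Features at 1 FPKM or more in at least 3 libraries were tested (11097). Values were tested as log2(FPKM + 1), on which scale changes of genes at low levels are understated. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with a mean per group, a variance trend and robust moderation, and p-values were adjusted by Benjamini-Hochberg to a threshold of 0.05. The 5 comparisons were KO against WT in TFH and in non-TFH cells, TFH against non-TFH cells in WT and in KO mice, and the difference between both KO against WT changes (the interaction). Each log2 change is given with its standard error (SE) from this fit, and each level with its standard deviation (SD) over 3 libraries unless another n is stated. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

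Data were simulated with a single spread per gene, taken from the fit to all 12 libraries. The fit then recovered 82.1% of genes changed by 2-fold in the TFH comparison of KO with WT and 70.1% in the non-TFH comparison. It recovered 79.1% in each comparison of TFH with non-TFH cells and 56.7% in the interaction. Of the calls in those simulations, 4 to 6.1% were false. Changes were simulated only in genes above a set mean level, and noise was drawn separately for each gene. The shares recovered therefore do not cover genes at low levels. In the data, TFH libraries of a group correlated less with each other than non-TFH libraries of a group. Neither the recovered nor the false shares cover such an unequal spread.

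The model, the 30 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered the TFH program, TFH-repressed and non-TFH genes, Th1, Th2, Th17 and Treg genes, and naive, activation and co-inhibitory genes. Further lists held cytokines, chemokine receptors, T cell receptor signalling, the ETS family, cell cycle, interferon response, immediate early genes, glycolysis, cholesterol synthesis and survival. They also covered markers of B cells, plasma cells, germinal centre B cells, macrophages, neutrophils, dendritic cells, CD8 T cells, NK cells, erythroid cells and platelets, and sex-linked genes. Of 502 list entries, 459 had a feature of their own, 9 were the main gene of a joint feature, 29 could not be separated from a neighbour and 5 had no entry. The 25 lists with at least 5 testable members were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists. camera with an estimated correlation, and fry, were run beside it. The genes named are Ets1, the 10 largest rises and 10 largest falls with a mean of at least 5 FPKM and no overlap between the groups, up to 4 members of each list with the smallest adjusted p, and 20 genes fixed by name. Predicted, small RNA, immunoglobulin, T cell receptor and mitochondrial genes were left out of the largest changes. Some genes that meet this rule are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Cxcr5 and Pdcd1 encode the sorted markers and are no finding between TFH and non-TFH cells.

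The alternatives were values as deposited, quantile normalization, pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, a fit to the compared groups alone, no trend and robust moderation, array weights, the highest entry of a gene, replicate blocks and leaving out each library. Further alternatives were chosen after the data were seen and are named as such. Labels and replicate numbers named no batch, and the numbers did not pair the libraries.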

Results

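RNA was sequenced from splenic TFH and non-TFH cells of WT mice and of mice labelled as lacking Ets1 in T cells, with 3 libraries in each of the 4 groups. Estimated depths were 11.9 to 14.2 M fragments in the TFH libraries and 13.6 to 15.5 M in the non-TFH libraries. Cell type was the main source of variation, with 66.9% of the variance of the tested genes on the first principal component and 12.1% on the second. No pair of libraries was identical.

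The Ets1 transcript was not lower in the libraries labelled KO. In non-TFH cells Ets1 (chromosome 9, 32696024 to 32757820, mm10), an ETS family transcription factor of lymphocytes, stood at 407 ± 5.11 FPKM in WT and 400 ± 18.2 in KO libraries (SD, n = 3 per group), a log2 change of -0.03 ± 0.1 (SE), with an exact two-sided permutation p of 0.8. In TFH cells it stood at 196 ± 23 FPKM in WT and 252 ± 25.9 in KO libraries, a log2 change of 0.37 ± 0.1 with an adjusted p of 0.015 from limma. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. The rise in TFH cells did not pass with quantile normalization (0.17, adjusted p = 0.2), with the TFH groups alone, or without KO TFH replicate 2 (0.32) or 3 (0.33), and its adjusted p ranged from 0.0057 to 0.2 over the alternatives. The gene's value covers exons that a floxed deletion can leave in place, so it checks nothing about the deletion. Genotypes are therefore given as labelled.

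TFH cells labelled KO were compared with WT TFH cells first. In the libraries labelled KO, Il4 (chromosome 11, 53612461 to 53618689), the cytokine that drives switching to IgG1 and IgE, rose from 32.9 ± 16.6 to 393 ± 115 FPKM (SD, n = 3 per group), a log2 change of 3.64 ± 0.38 (SE, adjusted p = 4.2e-05). Gata3, the transcription factor of type 2 helper cells, measured like Foxp3 and Cd74 jointly with an overlapping gene, rose from 29.9 ± 0.474 to 78 ± 20.3 FPKM (1.32 ± 0.15). Ifng, the type 1 effector cytokine, fell from 50.2 ± 13.7 to 10.4 ± 1.16 FPKM (-2.14 ± 0.29, adjusted p = 0.00024), and Foxp3 (chromosome X, 7573600 to 7595243), the regulator of regulatory T cells, fell from 56.5 ± 14.4 to 8.57 ± 1.82 FPKM (-2.57 ± 0.19, adjusted p = 2.9e-06). Bcl6, the transcription factor required for TFH cells, rose from 30.6 ± 4.08 to 50 ± 3.5 FPKM (0.7 ± 0.12, adjusted p = 0.0014). In the same comparison the macrophage and monocyte markers moved by a median log2 change of -2.19, and unnamed loci numbered 12338 to 25171 in WT and 7855 to 10233 in KO libraries.

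Of 26 measured genes of the TFH program, 13 rose, 5 fell and 8 did not pass (14 and 5 adjusted over the list alone), with a median of 0.41 and camera adjusted p = 0.03. The adjusted p was 0.39 with an estimated correlation, and the list did not pass with quantile normalization, with the filter at 5 FPKM or without WT TFH replicate 3. Sh2d1a, the adaptor SAP that TFH cells need to help B cells, rose from 373 ± 40.3 to 1040 ± 110 FPKM, and Pou2af1, a coactivator of lymphocytes, from 29.1 ± 2.11 to 134 ± 26.9 FPKM. S1pr2, a receptor that retains cells in follicles, rose by 1.76 ± 0.14 log2, Tox2 by 1.56 ± 0.26, Ascl2, which induces Cxcr5, by 1.25 ± 0.22, and Pdcd1, which encodes PD-1, by 0.85 ± 0.1. Against this direction, Angptl2 fell from 59.7 ± 3.44 to 6.72 ± 1.61 FPKM. Il21, the TFH cytokine that supports germinal centre B cells, fell by 0.53 log2 (SE 0.15, adjusted p = 0.022), a call lost with a pseudocount of 0.1, with array weights and without WT TFH replicate 1 or 3 or KO TFH replicate 1 or 3 (adjusted p 0.0038 to 0.17 over the alternatives). Maf (0 ± 0.19), Icos (0.24 ± 0.2) and Cxcr5 (-0.43 ± 0.99) did not pass. Cxcr5 stood at 252, 154 and 180 FPKM in WT and at 125, 143 and 157 in KO TFH libraries. The SE of Cxcr5 shares its spread with non-TFH libraries, which ranged from 0 to 12.2 FPKM, so this fit tests Cxcr5 in TFH cells poorly.

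Of 13 genes listed as TFH-repressed or non-TFH genes, 8 fell and none rose (9 fell and 1 rose adjusted over the list alone). Their median was -0.89 and camera adjusted p = 0.0028, or 0.21 with an estimated correlation. In WT mice 5 of the 13 were higher and 7 lower in TFH than in non-TFH cells. Ccr7, the receptor that holds T cells in the T zone, fell from 76.8 ± 6.87 to 20.5 ± 1.49 FPKM, Il7r, the receptor of the survival cytokine IL-7, from 39.6 ± 9.97 to 12.8 ± 5.22, and Il2ra, the high-affinity chain of the IL-2 receptor, from 15.5 ± 5.56 to 2.9 ± 0.42. Foxo1, a factor of quiescent T cells, fell by 0.89 log2 (SE 0.15). The naive and quiescence list, which shares several of these genes, had 9 of 19 members lower and 3 higher (10 and 4 adjusted over the list alone) and a median of -0.59. Its camera adjusted p of 0.038 became 0.39 with an estimated correlation, and the call was lost without WT TFH replicate 2 or 3 or KO TFH replicate 1 or 3.

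Genes of the other helper T cell types moved unequally. Of 17 type 1 genes 13 fell and none rose (13 and 1 adjusted over the list alone), with a median of -1.16 and camera adjusted p = 0.00027, or 0.059 with an estimated correlation. Besides Ifng, the chemokine receptor Cxcr3 fell from 142 ± 3.5 to 43.3 ± 7.65 FPKM. Tbx21, which encodes T-bet, fell by 0.78 log2 (SE 0.25, adjusted p = 0.031), a call lost with a pseudocount of 0.1, the TFH groups alone, array weights, without any of the 3 WT TFH libraries and without KO TFH replicate 1 (0.0093 to 0.11 over the alternatives). Of 13 type 2 genes 4 rose and 6 fell, as they did adjusted over the list alone, and the list test did not pass (adjusted p = 0.66). Its median was -0.38, its mean 0.28 and its camera direction downward. Of 8 type 17 genes 2 rose and 5 fell, the same counts as adjusted over the list alone (adjusted p = 0.49), among them Rora, a factor of type 17 cells, which fell by 1.43 log2, and Ccr6, a chemokine receptor, which fell by 1.38. Of 17 Treg genes 3 rose and 7 fell, again as adjusted over the list alone (adjusted p = 0.49). Ctla4, a receptor that restrains costimulation, fell from 182 ± 16.2 to 65.8 ± 4.82 FPKM, whereas Itgae, the integrin CD103, rose by 1.47 ± 0.27 and Il10 did not pass (0.02 ± 0.4). Beside these groups, Y-linked genes were listed at 0 in all KO TFH libraries and present in the WT TFH libraries.

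Proliferation and glycolysis genes were higher in KO TFH cells. Of 29 cell cycle genes 18 rose and none fell (21 and 0 adjusted over the list alone), with a median of 0.77 and camera adjusted p = 5.5e-06, or 0.39 with an estimated correlation. Birc5, the mitotic protein survivin, rose from 52.9 ± 9.54 to 122 ± 6.13 FPKM and Top2a, the topoisomerase of dividing cells, from 31.4 ± 3.9 to 67 ± 11.4. Of 16 glycolysis genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.64 and camera adjusted p = 0.00021, or 0.39 with an estimated correlation. The enzymes Tpi1 (103 ± 1.38 to 402 ± 57.2 FPKM), Aldoa (411 ± 17 to 771 ± 90.5) and Gapdh (978 ± 107 to 1800 ± 142) all rose. The immediate early list, which also responds to tissue dissociation, moved the other way, with 10 of 21 members lower and 1 higher (11 and 1 adjusted over the list alone), a median of -1.2 and camera adjusted p = 0.0032, or 0.39 with an estimated correlation. Klf6 fell from 163 ± 64.1 to 40.1 ± 6.73 FPKM and Ier2 from 185 ± 3.93 to 87.9 ± 9.96, both rapidly induced transcription regulators. The shift of the macrophage markers stood beside each of these groups too.

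Some components of T cell signalling changed in opposite directions, and their lists did not pass. Of 21 receptor signalling genes 5 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.75). Cd247, the zeta chain of the receptor, rose from 260 ± 11.3 to 625 ± 35.8 FPKM (adjusted p = 2.8e-07), the activator Rasgrp1 by 0.97 ± 0.11 and the kinase Fyn by 0.87 ± 0.12, while the phospholipase Plcg1 fell by 1.09 log2. Among 16 ETS family genes 6 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.58), with Ets2 at 1.26 ± 0.16 and Etv5 (n = 2 in WT) at 1.22 ± 0.15. Cytokine genes went both ways (5 of 17 rose and 7 fell, as adjusted over the list alone, camera adjusted p = 0.59), with Ltb, a lymphoid tissue cytokine, falling from 387 ± 49.8 (n = 2) to 56.1 ± 14.4 FPKM and Tnf by 1.65 log2. So did activation genes (7 of 20 rose and 6 fell, as adjusted over the list alone, camera adjusted p = 0.75). Anxa2, a membrane-binding protein of activated cells, rose from 157 ± 16 to 824 ± 55.3 FPKM and Lgals1, a galectin, from 270 ± 14.6 to 985 ± 260, whereas Cd38, an ectoenzyme, fell from 43 ± 13.5 to 4.59 ± 0.887 and Il2rb, a chain of the IL-2 and IL-15 receptors, by 0.92 log2. Among the largest falls were Thy1 (chromosome 9, 44043384 to 44048581), the T cell surface protein CD90, from 32.5 ± 8.29 to 1.59 ± 0.325 FPKM, and Gmfg, an actin regulator of blood cells, from 133 ± 26.7 to 9.27 ± 2.73. Of the 10 largest rises 4, and of the 10 largest falls 3, were of genes listed at 0 in every library of a group, such as Stard5 (0 in each WT TFH library and 29.1, 33.7 and 30.8 FPKM in the KO TFH libraries).

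Transcripts typical of other blood cells differed as well. Of 18 macrophage and monocyte markers 15 fell and 3 rose, as adjusted over the list alone, with camera adjusted p = 1.5e-08, or 0.21 with an estimated correlation. Csf1r, the receptor of macrophage colony-stimulating factor, fell from 152 ± 30.2 to 19.3 ± 2.02 FPKM, and Slc40a1, the iron exporter of macrophages, from 276 ± 146 to 22.2 ± 7.15. Of the complement genes, chosen after their values were seen, C1qb fell by 2.39 log2 and C1qc by 2.4. Itgam, the integrin CD11b, rose from 1.35 ± 0.5 to 27.6 ± 2.89 FPKM. Lyz1 and Lyz2, lysozymes chosen after their values were seen, rose by 1.94 and 1.07 log2 (n = 2 in WT), and the rise of Lyz2 did not pass in 7 of 24 alternatives, among them leaving out WT TFH replicate 1 or 3 or KO TFH replicate 1 or 3 (adjusted p 0.0035 to 0.31). Of 14 B cell markers 7 fell and none rose (8 and 0 adjusted over the list alone), with a median of -0.71 and camera adjusted p = 0.0032, or 0.21 with an estimated correlation. Cd74, the invariant chain of MHC class II, fell from 1060 ± 176 to 487 ± 38.3 FPKM, a call lost with array weights (adjusted p = 0.067, range 7.9e-05 to 0.067), and Cd22 from 23.7 ± 9.3 to 3.04 ± 0.382. Ms4a1 (-0.06), chosen after its values were seen, did not pass. Of 7 dendritic cell markers 3 fell and none rose (4 and 0 adjusted over the list alone), with a median of -1.02 and camera adjusted p = 0.023, or 0.39 with an estimated correlation and lost without KO TFH replicate 3. Of 11 CD8 and cytotoxic genes 3 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.49), and Cd8b1 rose from 8.4 ± 2.12 to 39.8 ± 5.29 FPKM.

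The other lists did not pass in TFH cells. Chemokine and homing receptors fell in 9 of 20 and rose in 3 cases (10 and 3 adjusted over the list alone, camera adjusted p = 0.13). Co-inhibitory genes rose in 3 of 15 and fell in 6 cases (5 and 6 adjusted over the list alone), with a median of 0.01, a mean of -0.27 and camera adjusted p = 0.59. Interferon response genes rose in 2 of 21 and fell in 3 cases, as adjusted over the list alone, with a median of 0.04, a downward camera direction and adjusted p = 0.75. Survival genes rose in 3 of 18 and fell in 5 cases (4 and 5 adjusted over the list alone, adjusted p = 0.75). Cholesterol synthesis genes rose in 2 of 19 and fell in 2 cases (0 and 2 adjusted over the list alone, adjusted p = 0.49), and in non-TFH cells 1 rose and 3 fell, as adjusted over the list alone (adjusted p = 0.18). Plasma cell markers rose in 1 and fell in 1 of 5 cases (adjusted p = 0.75), and in non-TFH cells 3 rose (adjusted p = 0.056), with the same counts adjusted over the list alone. Of 7 neutrophil markers limma called 0 in TFH cells (0 at an unadjusted p under 0.05, camera adjusted p = 0.75) and 2 higher in non-TFH cells (camera adjusted p = 0.14). Of 7 dendritic cell markers it called 0 in non-TFH cells (2 at an unadjusted p under 0.05, camera adjusted p = 0.38). Lists too short for camera were counted only. Of 4 NK markers 3 fell and 1 rose in TFH cells, and 1 rose in non-TFH cells (4 adjusted over the list alone). The NK list shares Tyrobp with the macrophage list and Il2rb with the activation list. Of 3 germinal centre B cell markers 1 rose in TFH cells (S1pr2, also a TFH program gene), and limma called 0 in non-TFH cells (2 at an unadjusted p under 0.05). Of 5 sex-linked genes 4 fell in TFH cells and 0 were called in non-TFH cells (0 unadjusted). limma called 0 of 3 erythroid markers in either cell type (0 unadjusted in each), and 0 of 3 platelet markers (0 unadjusted in TFH and 1 in non-TFH cells).

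In all, limma called 3431 of 11097 genes changed in TFH cells, 1755 higher and 1676 lower in the libraries labelled KO, and 1270 of them by at least 2-fold. The WT and KO libraries did not overlap for 38% of genes, where chance gives 10%. The count was 2173 when the TFH groups alone were fitted, 2237 with array weights and 1725 with the number of unnamed loci as a covariate. Fitting the 6 TFH libraries with the mean B cell or macrophage marker level as a covariate left 0 calls each in limma (961 and 843 at an unadjusted p under 0.05). Both marker lists differ between the genotypes themselves, with Csf1r at 133, 187 and 136 FPKM in WT and 19.9, 17 and 20.9 in KO libraries. Such a covariate removes genotype differences of any cause, so the lost calls do not show that other cells caused them. With Ddx3y, a Y-linked gene, as the covariate 394 were called, against 2173 for the same libraries without a covariate. Ddx3y is listed at 0 in every KO TFH library and present in every WT TFH library, so the same limit holds for it. All of these covariates were chosen after the data were seen. Without WT TFH replicate 1, the library with high Y-linked genes, 3353 were called. Sex and genotype were partly confounded in the TFH groups, as the levels of the Y-linked genes show.

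**Figure D1:**
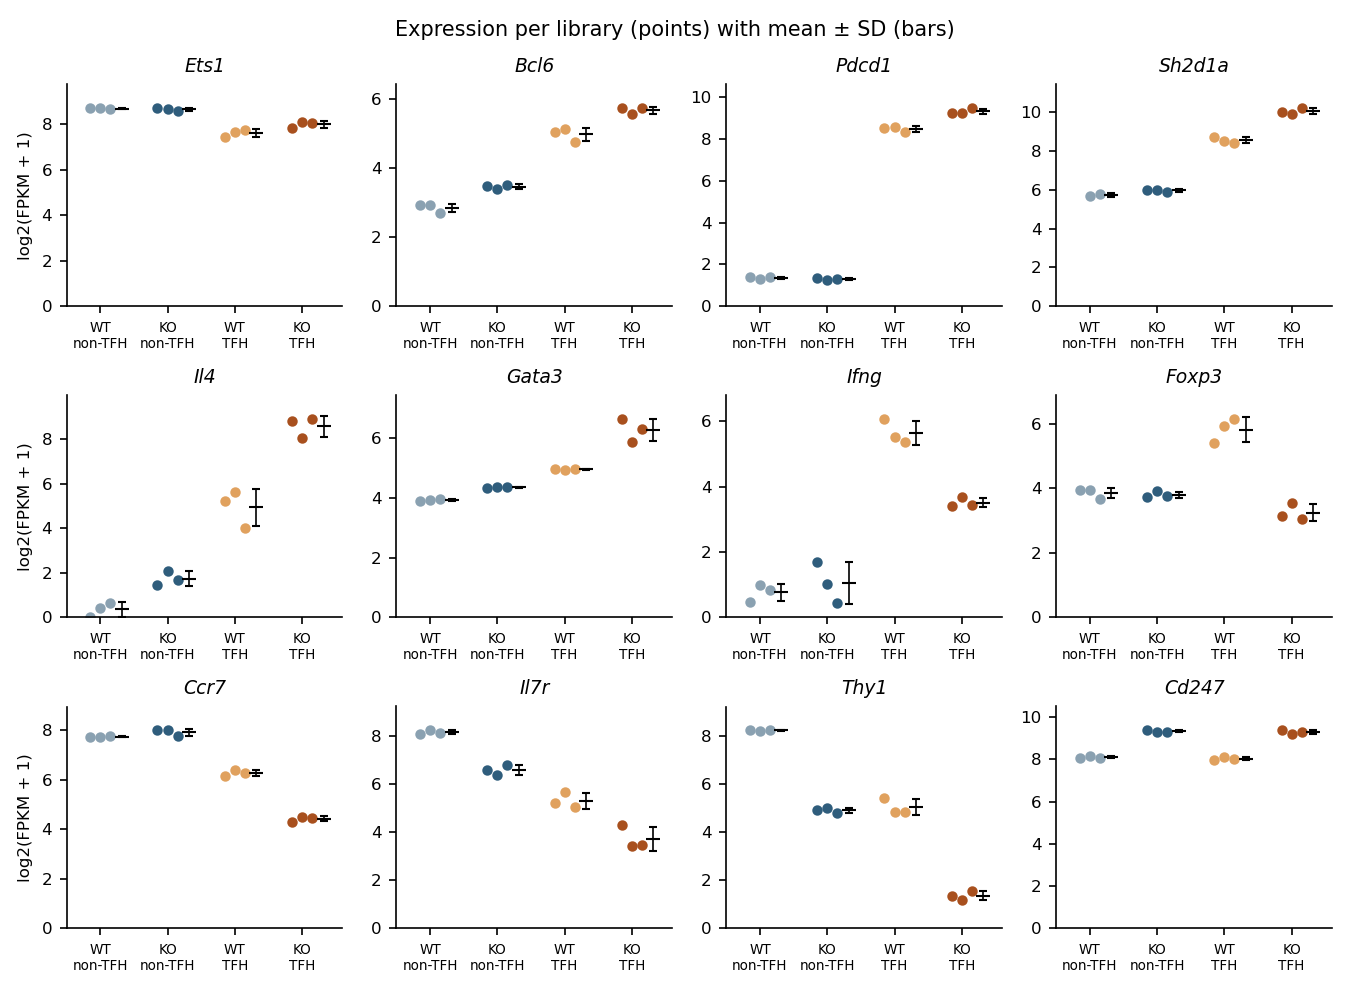
Levels of 12 genes as log2(FPKM + 1) on the y axis in the 4 groups on the x axis, with a point per library and the mean ± SD as bars. Il4 and Gata3 lie higher and Ifng, Foxp3 and Ccr7 lower in KO than in WT TFH cells, and Thy1 lies lower in the KO groups of both cell types.

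Non-TFH cells labelled KO were compared with WT non-TFH cells to ask what changed outside the TFH gate. The largest rise of a gene measured in both groups was that of Tns4, a tensin, from 0.209 ± 0.108 to 125 ± 5.39 FPKM (SD, n = 3 per group; log2 change 6.71 ± 0.14 SE, adjusted p = 1.2e-10). Itgae rose from 1.25 ± 0.544 to 66.2 ± 10.3 FPKM, Lgals3, a galectin, from 1.71 ± 0.183 to 145 ± 27.6, and the inhibitory receptor Tigit from 0.5 ± 0.165 to 27.3 ± 3.44. Il7r fell from 287 ± 16.3 to 95.6 ± 13.6 FPKM, the kinase Fyn from 145 ± 9.73 to 33.1 ± 4, and H2-Ob, a chain of the peptide-loading regulator H2-O, from 34 ± 1.68 to 0.47 ± 0.164. Thy1 (298 ± 1.64 to 29 ± 2.09) and Gmfg (154 ± 2.43 to 27.8 ± 2.56), chosen after their values were seen, fell here as in TFH cells. The macrophage list had a median of 0.79 log2 here, with 8 of 18 members higher, and its call did not hold with an estimated correlation (adjusted p = 0.28).

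The lists of Treg and co-inhibitory genes, which share Ctla4 and Nt5e, were both called higher by camera with the preset correlation. Of 17 Treg genes 10 rose and none fell (10 and 1 adjusted over the list alone), with a median of 0.91 and camera adjusted p = 8.7e-06, or 0.15 with an estimated correlation. Nt5e, the ectoenzyme CD73, rose from 12.8 ± 0.285 to 108 ± 2.82 FPKM, the costimulatory receptor Tnfrsf9 from 3.53 ± 0.532 to 42.1 ± 2.56, and Klrg1, a receptor of differentiated lymphocytes, from 0.176 ± 0.104 to 10 ± 4.11. The regulator Foxp3 itself did not pass (13.5 ± 1.54 and 13 ± 0.912 FPKM, log2 change -0.05 ± 0.19). Of 15 co-inhibitory genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.94 and camera adjusted p = 3.3e-05, a call that held with an estimated correlation (adjusted p = 0.029). Of 20 activation genes 12 rose and 4 fell, as adjusted over the list alone (median 0.67, camera adjusted p = 0.00019, or 0.086 with an estimated correlation), among them Anxa2 (5.24 ± 0.877 to 109 ± 10.2 FPKM), Lgals1 (49 ± 5.93 to 530 ± 28.5) and Il2rb (30 ± 1.2 to 90.8 ± 2.02).

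Lists of helper T cell genes were mixed, and none of their calls held with an estimated correlation. Of 26 TFH program genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.39 and camera adjusted p = 0.0035, or 0.17 with an estimated correlation. Il6st, the signalling chain gp130, rose from 64.8 ± 2.66 to 122 ± 5.44 FPKM, Batf, a factor of activated T cells, from 27 ± 2.59 to 63.3 ± 12.6, the adhesion receptor Slamf6 from 79.8 ± 7.55 to 173 ± 13.7, and Bcl6 from 6.23 ± 0.607 to 10 ± 0.501. Tox2 rose by 2.01 ± 0.26 log2 and Maf by 0.88 ± 0.19, and Pdcd1 did not pass (-0.06 ± 0.1). Il21 rose by 0.49 ± 0.15 to a level of 0.678 ± 0.258 FPKM (adjusted p = 0.043), but the call was lost in 12 of 24 alternatives (0.0035 to 0.47), including without any of the 6 non-TFH libraries or KO TFH replicate 1 or 3. The list of TFH-repressed and non-TFH genes did not pass (2 of 13 rose and 3 fell, or 3 and 3 adjusted over the list alone, camera adjusted p = 0.94). Of 13 type 2 genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.96, camera adjusted p = 0.0048, or 0.17 with an estimated correlation). The chemokine receptor Ccr8 rose from 1 ± 0.607 to 22.1 ± 1.69 FPKM, Ccr4 by 1.88 ± 0.19 log2 and Il4ra, the receptor of IL-4, from 81.4 ± 13.8 to 191 ± 27.7 FPKM. Il4 rose by 1.37 ± 0.38 log2 to 2.38 ± 0.801 FPKM (adjusted p = 0.026), a call lost in 7 of 24 alternatives (0.00082 to 0.36), among them without WT non-TFH replicate 1 or 2 or KO non-TFH replicate 2 or 3, and Gata3 did not pass (0.42 ± 0.15, adjusted p = 0.079). Of 8 type 17 genes 3 rose and none fell, as adjusted over the list alone (camera adjusted p = 0.0087, or 0.17 with an estimated correlation and lost with the filter at 5 FPKM), with Rora at 2.02 ± 0.24 and Ccr6 at 1.32 ± 0.22. Of 17 type 1 genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.14). Ifng did not pass (0.29 ± 0.29).

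Cell cycle genes rose (15 of 29, none fell, or 19 and 0 adjusted over the list alone; median 0.77, camera adjusted p = 4.9e-06, or 0.28 with an estimated correlation), with Birc5 at 1.44 ± 0.14 and Top2a at 1.4 ± 0.16 log2. Of 21 immediate early genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.03, camera adjusted p = 0.00035, or 0.24 with an estimated correlation), including Egr1 (24.2 ± 1.4 to 89.6 ± 16.9 FPKM) and Nr4a1 (19.5 ± 0.95 to 228, 79.4 and 84.4), both induced by receptor signalling. Without KO non-TFH replicate 1, the highest of these, the log2 change of Nr4a1 was 2.02, against 2.51 with it. Of 21 interferon response genes 8 rose and none fell (13 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.0029, or 0.39 with an estimated correlation). The antiviral genes Oasl2 (12.4 ± 2.49 to 45.7 ± 9.87 FPKM) and Mx1 (9.1 ± 2.97 to 34.7 ± 7.94) were among them. Survival genes rose as a list (5 of 18 rose and 1 fell, or 6 and 1 adjusted over the list alone; camera adjusted p = 0.022, or 0.17 with an estimated correlation and lost without WT non-TFH replicate 3), with the anti-apoptotic Bcl2l1 at 1.76 ± 0.14 and Bcl2 at 1.08 ± 0.13. Chemokine and homing receptors rose as well (8 of 20 rose and 3 fell, or 9 and 3 adjusted over the list alone; camera adjusted p = 0.016, or 0.19 with an estimated correlation and lost without WT non-TFH replicate 2). Ccr9, a gut-homing receptor, was listed at 0 in each WT non-TFH library and at 104, 96.8 and 107 FPKM in the KO libraries. Markers of macrophages rose beside these groups (8 of 18 rose and 1 fell, or 13 and 1 adjusted over the list alone; camera adjusted p = 0.0011, or 0.28 with an estimated correlation), with Csf1r at 1.02 ± 0.22 and Itgam at 1.16 ± 0.17. B cell markers did not pass as a list (4 of 14 rose and none fell, as adjusted over the list alone; camera adjusted p = 0.066), though Cd74 rose from 10 ± 3.16 to 24.3 ± 4.71 FPKM.

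Receptor signalling genes had no common direction (4 of 21 rose and 7 fell, or 5 and 7 adjusted over the list alone; median -0.04, camera adjusted p = 0.25). Cd247 rose from 275 ± 11.9 to 641 ± 19.1 FPKM and Rasgrp1 by 1.1 ± 0.11 log2, and Cd5, a negative regulator of signalling, fell from 276 ± 6.87 to 119 ± 2.37 FPKM. Of 16 ETS family genes 6 rose and none fell, as adjusted over the list alone (camera adjusted p = 0.056), with Etv5 at 2.1 ± 0.14 and Ets2 at 1.06 ± 0.16. Glycolysis genes did not pass as a list (2 of 16 rose and 4 fell, or 2 and 6 adjusted over the list alone; camera adjusted p = 0.25): Aldoa fell by 0.7 log2 and Tpi1 rose by 0.8 ± 0.12. Neither did cytokines (5 of 17 rose and 4 fell, as adjusted over the list alone; camera adjusted p = 0.4), where Il10 rose by 2.44 ± 0.4 and Ltb and Tnf fell by 1.68 and 0.73 log2, nor naive genes (3 of 19 rose and 3 fell, or 5 and 3 adjusted over the list alone; camera adjusted p = 0.38), with Ccr7 at 0.19 ± 0.1. Cytotoxic genes parted (3 of 11 rose and 3 fell, or 4 and 3 adjusted over the list alone; median 0.22, mean 0.3, camera direction downward, adjusted p = 0.79). Gzmb, a granzyme, rose from 0.427 ± 0.137 to 49.8 ± 6.28 FPKM, Nkg7 from 4.84 ± 1.22 to 37.7 ± 2.8 and Cd8b1 from 11.8 ± 2.5 to 101 ± 5.47, while the NK receptor Klrd1 fell from 24.6 ± 1.89 to 2.08 ± 0.777. Perforin (Prf1), chosen after its values were seen, fell from 11.8 ± 0.366 to 1.21 ± 0.368 FPKM, and Cd8a, so chosen, stood at 0.0867 and 0.258 FPKM in WT and KO cells.

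In non-TFH cells limma called 2264 genes changed, 1312 higher and 952 lower in the libraries labelled KO (1509 and 765 with the values as deposited), and 947 by at least 2-fold. The WT and KO libraries did not overlap for 52.1% of genes, where chance gives 10%. The count was 3890 when the non-TFH groups alone were fitted and 4167 with array weights. Both of these fits called more genes here than in TFH cells, the reverse of the main fit, which shares its spread over all 12 libraries. Libraries of a group correlated at 0.96 to 0.9763 in TFH and at 0.9785 to 0.9858 in non-TFH cells. Which cell type had more changed genes is therefore not shown, and the calls in both depend on the shared spread.

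**Figure D2:**
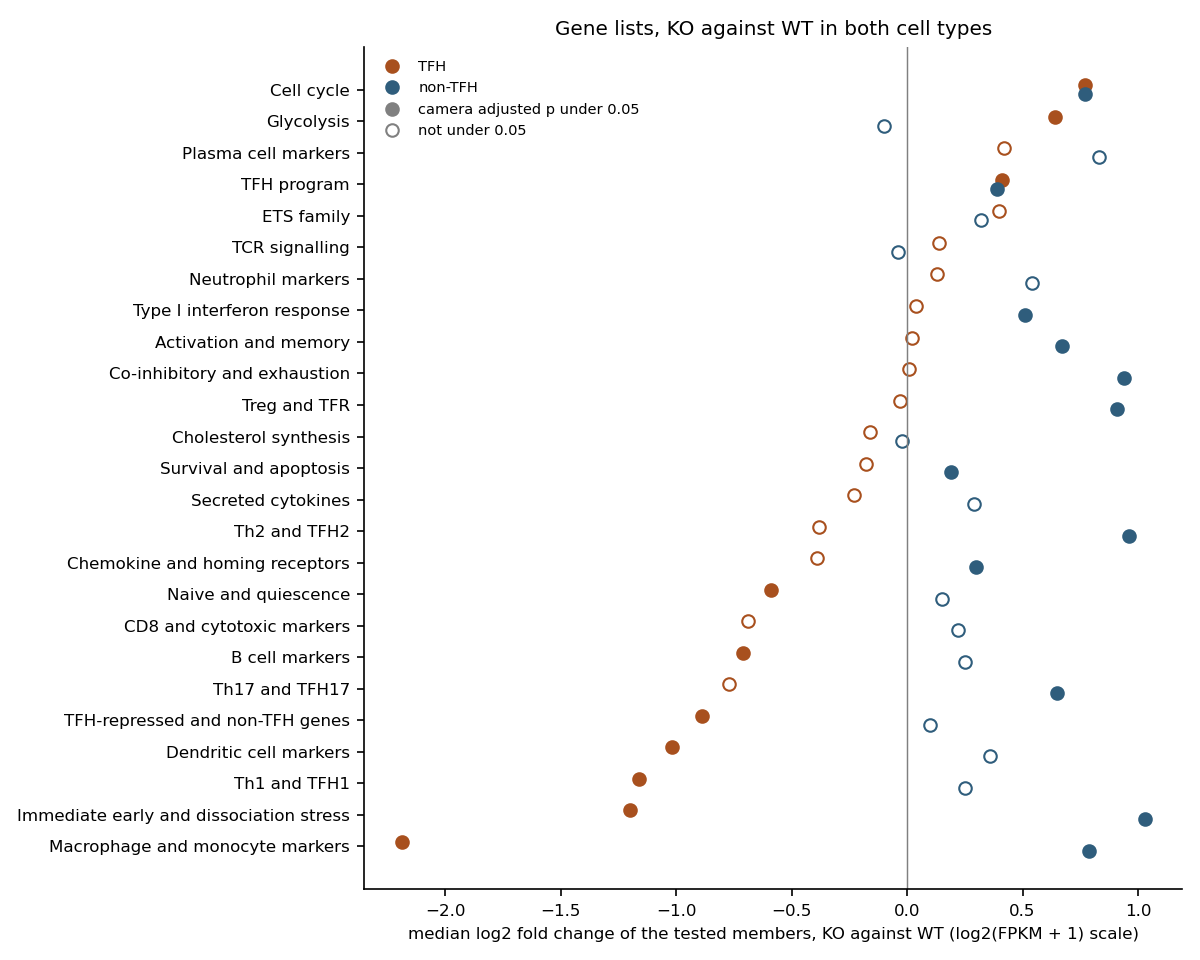
Median log2 fold change, KO against WT, of 25 gene lists on the x axis, in TFH cells (brown) and non-TFH cells (blue). Filled points passed camera with the preset correlation, and the macrophage list lies at -2.19 in TFH and 0.79 in non-TFH cells.

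The 2 cell types of WT mice were compared to place these changes beside the normal TFH profile. TFH cells had higher Il21 (69.8 ± 8.63 against 0.187 ± 0.0903 FPKM, SD, n = 3 per group; log2 difference 5.89 ± 0.15 SE, adjusted p = 1.1e-10), Bcl6 (30.6 ± 4.08 against 6.23 ± 0.607) and Icos (172 ± 58.8 against 17.7 ± 0.37), an activation receptor of TFH cells. They had lower Ccr7 (76.8 ± 6.87 against 211 ± 2.9 FPKM) and Il7r (39.6 ± 9.97 against 287 ± 16.3). Pdcd1 and Cxcr5, which encode the sorted markers, differed by 7.1 ± 0.1 and 5.12 ± 0.99 log2 and are no finding. Ets1 was lower in TFH cells, by a log2 difference of -1.06 ± 0.1 (adjusted p = 1.7e-06).

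Of 26 TFH program genes 24 were higher and 1 lower, as adjusted over the list alone (median 2.69, camera adjusted p = 4.3e-09), a call that held with an estimated correlation (adjusted p = 0.019). Of 19 naive genes 16 were lower and 2 higher, as adjusted over the list alone (median -1.49, adjusted p = 2.2e-06, and 0.038 with an estimated correlation), among them Igfbp4 (334 ± 22.6 against 15.9 ± 5.33 FPKM). Co-inhibitory genes (15 of 15 higher), cytokines (15 of 17 higher and 1 lower) and activation genes (16 of 20 higher and 3 lower), with the same counts adjusted over each list alone, passed with a preset and with an estimated correlation (adjusted p = 0.016, 0.038 and 0.03). Tigit differed by 5.77 ± 0.14 log2, Ifng by 4.88 ± 0.29 and the calcium-binding S100a11 by 4.03 ± 0.1. Cell cycle genes were higher (28 of 29, or 29 adjusted over the list alone; median 3.1, camera adjusted p = 9.6e-10, or 0.18 with an estimated correlation), such as Birc5 (52.9 ± 9.54 against 1.05 ± 0.116 FPKM). Treg genes (14 of 17 higher, adjusted p = 2.7e-06), type 17 genes (6 of 8, 0.0054), type 1 genes (13 of 17 higher and 2 lower, 0.032) and glycolysis genes (12 of 16 higher and 1 lower, 0.0053), each with the same counts adjusted over the list alone, were higher as lists. Their adjusted p values were 0.064, 0.073, 0.093 and 0.36 with an estimated correlation. Immediate early genes were higher in 15 of 21 and lower in 4 cases (16 and 4 adjusted over the list alone; adjusted p = 0.022, or 0.36 with an estimated correlation).

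Transcripts of other cell types stood beside all of these groups in WT TFH libraries. All 14 measured B cell markers were higher, as adjusted over the list alone (median 3.3, camera adjusted p = 2.2e-06, and 0.019 with an estimated correlation), with Cd74 at 1060 ± 176 against 10 ± 3.16 FPKM. Of 18 macrophage markers 17 were higher and 1 lower, as adjusted over the list alone (median 4.42, adjusted p = 2.2e-06, or 0.17 with an estimated correlation), with C1qb at 293 ± 101 against 2.63 ± 0.526 FPKM. All 5 plasma cell markers were higher, as adjusted over the list alone (adjusted p = 0.036, or 0.32 with an estimated correlation). The lists of repressed genes, type 2 genes, interferon response, receptor signalling, ETS family, cholesterol synthesis, survival, chemokine receptors, neutrophil, dendritic and cytotoxic markers did not pass (adjusted p = 0.47, 0.17, 0.074, 0.14, 0.24, 0.62, 0.81, 0.13, 0.11, 0.082 and 0.76). Of 5 sex-linked genes 3 were lower in TFH cells (median -2.29), so that sex moves with cell type here. In all, 7501 of 11097 genes differed, 3922 higher and 3579 lower in TFH cells, or 4971 higher and 2729 lower with the values as deposited, and the groups did not overlap for 72% of genes, where chance gives 10%.

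**Figure D3:**
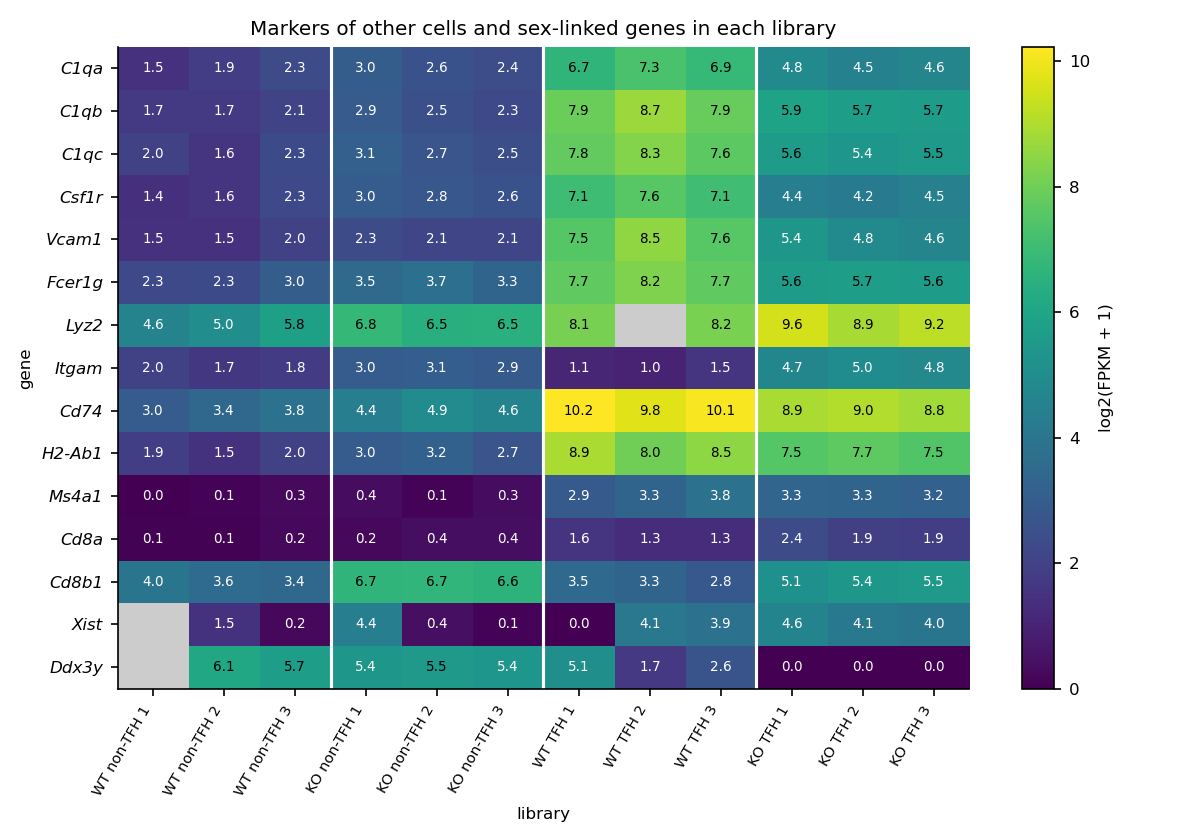
Heat map of log2(FPKM + 1) per library for markers of macrophages, B cells, CD8 T cells and sex, with libraries on one axis and genes on the other, and grey where no entry was used. C1qa, C1qb, C1qc, Csf1r, Cd74 and H2-Ab1 are highest in the WT TFH libraries, whereas Itgam and Lyz2 are highest in the KO TFH libraries.

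In mice labelled KO the same comparison asked how TFH cells differ from their non-TFH counterparts. Il4 stood at 393 ± 115 against 2.38 ± 0.801 FPKM (SD, n = 3 per group; log2 difference 6.85 ± 0.38 SE, adjusted p = 3.9e-08), Sh2d1a at 1040 ± 110 against 61.1 ± 3.13 and S1pr2 at 101 ± 9.36 against 2.31 ± 0.102. Ccr7 was lower (20.5 ± 1.49 against 241 ± 22.3), as were Foxo1 (7.59 ± 1.9 against 85.4 ± 9.96) and Igfbp4 (4.36 ± 1.68 against 478 ± 43). Foxp3, higher in TFH cells of WT mice (1.97 ± 0.19), was lower in those of KO mice (-0.56 ± 0.19, adjusted p = 0.022), a call lost in 5 of 24 alternatives, among them without KO non-TFH replicate 2 or KO TFH replicate 1 or 3 (0.0071 to 0.2). Ets1 was lower in TFH cells, at -0.67 ± 0.1.

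TFH program genes (24 of 26 higher and 1 lower, median 2.61, camera adjusted p = 9.7e-09) and naive genes (16 of 19 lower, median -2.54, 8.5e-08), counts that were the same adjusted over the list alone, held with an estimated correlation (adjusted p = 0.034 for each). So did B cell markers (14 of 14 higher, as adjusted over the list alone, median 2.62, camera adjusted p = 2.2e-05, and 0.034 with an estimated correlation). All 29 cell cycle genes were higher, as adjusted over the list alone (camera adjusted p = 2.1e-10, or 0.23 with an estimated correlation). Glycolysis genes were higher in 14 of 16 cases, as adjusted over the list alone (median 1.88, adjusted p = 4.3e-05, or 0.23 with an estimated correlation), with Aldoa at 2.89 ± 0.09 log2. Interferon response genes were lower in 16 of 21 cases, as adjusted over the list alone (median -1.17, adjusted p = 0.0012, or 0.44 with an estimated correlation). Cytokines (12 of 17 higher and 2 lower, adjusted p = 0.00047), activation genes (11 of 20 higher and 4 lower, 0.023), receptor signalling genes (15 of 21 higher and 3 lower, 0.023) and macrophage markers (13 of 18 higher, 0.0019) were higher as lists, with adjusted p of 0.12, 0.22, 0.23 and 0.41 with an estimated correlation. Adjusted over the list alone the counts were the same, except 12 higher activation genes. No other list passed. Of 5 sex-linked genes 4 were lower in TFH cells, the Y-linked ones that are listed at 0 in the KO TFH libraries. Sex thus moves with cell type here too. In all, 7456 genes differed, 3724 higher and 3732 lower in TFH cells, or 4584 higher and 3007 lower with the values as deposited, and the groups did not overlap for 73.7% of genes, where chance gives 10%.

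The interaction asked whether the KO against WT change differed between the cell types. It passed for 1936 of 11097 genes, 763 with a higher and 1173 with a lower change in TFH than in non-TFH cells. Levels of sex-linked genes differ between these groups too. Il4 had a difference of 2.26 log2, with the higher change in TFH cells. In non-TFH cells it stood at 0, 0.336 and 0.57 FPKM in WT and at 1.71, 3.26 and 2.15 in KO libraries. The log2(FPKM + 1) scale understates a change at such levels, so a larger fold rise in TFH cells is not shown. Foxp3 (-2.53), Ctla4 (-2.7), Ifng (-2.42) and Ccr7 (-2.04) moved lower in TFH than in non-TFH cells, and Fyn (2.97) moved the other way. The changes of Bcl6 (0.09, adjusted p = 0.8), Cd247 (0.04, 0.82), Il7r (-0.01, 0.99) and Thy1 (-0.35, 0.32) did not pass a test of difference. Of the lists, type 1, Treg, activation, co-inhibitory and B cell genes held a negative difference with an estimated correlation (adjusted p = 0.013, 0.048, 0.048, 0.013 and 0.048). In the B cell list 6 of 14 members had a lower change and 8 did not pass in limma. Cd74 (-2.33), H2-Ab1 (-2.08), both of MHC class II, and Cd22 (-2.77) passed. Cd79b (-0.61, adjusted p = 0.11) and Ms4a1 (-0.21, 0.71) did not.

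Across the 11097 genes the 2 changes correlated with Pearson's r = 0.31 and Spearman's rho = 0.3. Genes are not independent replicates. Both comparisons called 1191 genes. Of these 520 rose in both, against 207 for independent calls, and 453 fell in both, against 144, while 68 rose in TFH and fell in non-TFH cells, against 151, and 150 did the opposite, against 198.

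**Figure D4:**
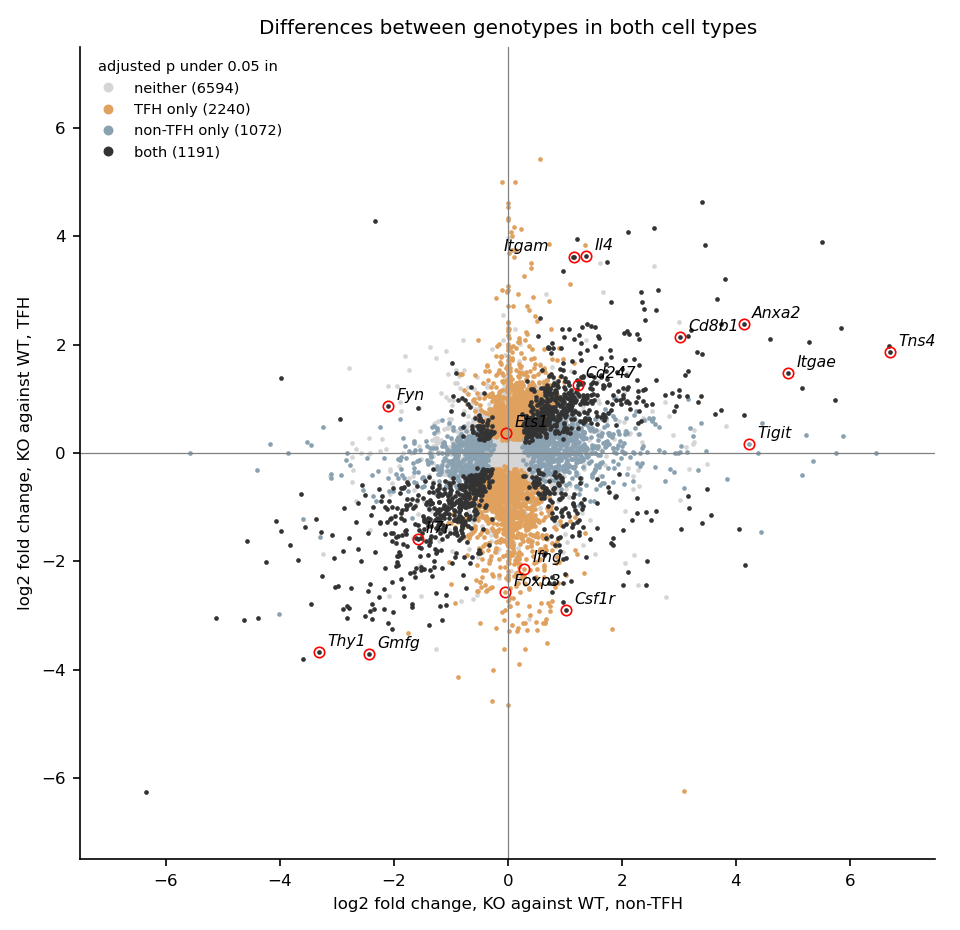
Log2 fold change, KO against WT, in non-TFH cells (x axis) and TFH cells (y axis) for 11097 genes, coloured by the comparison that called them, with named genes circled in red. Both comparisons called 1191 genes, most of them in the same direction.

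The series title speaks of a raised TFH profile, and this was measured with the genes that differed at least 2-fold between TFH and non-TFH cells. The 2276 genes higher in WT TFH cells moved by a median of 0.077 log2 in KO against WT TFH cells, with 563 higher and 578 lower, which camera did not call. The 2138 genes higher in KO TFH cells moved by a median of 0.384, with 852 higher and 207 lower, and camera called them higher. Each definition shares libraries with the comparison, which gave medians of -0.022 and 0.022 in 50 simulations without a genotype effect. With a 4-fold threshold the WT-defined genes moved by -0.177 and camera called them lower, whereas the KO-defined genes moved by 0.673 (321 higher and 62 lower) and it called them higher. The same simulations gave -0.034 and 0.032 for these, and the direction in TFH cells depended on the definition. These simulations held no genotype effect. Where the genotypes do differ, picking genes by their level in a genotype shifts them further, which was not simulated. The macrophage list had a median of 4.42 between TFH and non-TFH cells of WT mice and of -2.19 in KO against WT TFH cells, and neither call held with an estimated correlation (adjusted p = 0.17 and 0.21). In non-TFH cells both definitions moved upward, by 0.273 with the WT-defined genes (553 higher and 82 lower) and by 0.149 with the KO-defined genes, and camera called both higher. The simulations gave 0.021 and -0.022 for these. With a 4-fold threshold the medians in non-TFH cells were 0.492 and 0.205, and camera again called both higher. The genes lower in WT TFH cells moved by -0.121 in non-TFH cells, which camera called lower, and by 0.028 in TFH cells, which it did not call. The genes lower in KO TFH cells went the other way round, by -0.075 in TFH cells, which camera called lower, and by 0.009 in non-TFH cells, which it did not call.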

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

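The tests of macrophage RNA, of Itgam, Lyz1 and Lyz2 and of undeleted Ets1 exons were chosen after the result was seen. What brought the values of this part forward is a difference between the cell types, measured as an interaction, in the change of KO against WT libraries. A positive value means a higher change in TFH than in non-TFH cells. The interaction was called for 1936 genes, and 1 of 100 splits drawn in both cell types, the real one, gave as many, with 815 as the highest other. These splits mix the WT and KO labels within each cell type, so they ask about any genotype effect. They do not ask whether the effects are equal in both cell types, so they cannot exclude chance for the interaction. For the other comparisons the real split was the 1 with the most called genes, at 3431 for KO against WT in TFH cells (highest other 7), 2264 in non-TFH cells (7), 7501 between TFH and non-TFH cells of WT mice (3) and 7456 of KO mice (3), and there are too few splits for a share under 0.05.

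Of 25 lists, 17 had an interaction by camera with the preset correlation. With an estimated correlation 5 of them held, those of type 1, Treg, activation, co-inhibitory and B cell genes, and the others were not called (adjusted p = 0.064 to 0.39). The median was lower in TFH cells for genes of type 1 cells (-1.87), Treg cells (-1.76), type 17 cells (-1.14) and type 2 cells (-1.01), for TFH-repressed (-0.68), naive (-0.36), activation (-1.35) and co-inhibitory genes (-1.69), and for interferon response (-0.52), immediate early (-1.51), survival (-0.33) and chemokine receptor genes (-1.25). It was lower for markers of macrophages (-2.99), dendritic cells (-1.45), plasma cells (-1.28) and B cells (-0.72), and higher for glycolysis genes (0.86).

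Of 86 genes named for KO against WT, 67 had an interaction. Among type 2 genes these were Il4 (2.26), Gata3 (0.9), Il4ra (-1.32), Ccr4 (-2.7) and Ccr8 (-4.71). In the TFH program they were S1pr2 (1.69), Pou2af1 (1.63), Ascl2 (1.25), Sh2d1a (1.24) and Pdcd1 (0.91), with Slamf6 (-0.65), Batf (-0.87), Maf (-0.88), Il21 (-1.02), Il6st (-1.31) and Angptl2 (-3.38) on the other side. Among genes of other helper and regulatory T cells they were Ifng (-2.42), Cxcr3 (-2.12), Rora (-3.45), Ccr6 (-2.69), Foxp3 (-2.53), Ctla4 (-2.7), Itgae (-3.44), Il10 (-2.42), Nt5e (-2.97), Tnfrsf9 (-2.93), Klrg1 (-4.18) and Tigit (-4.07). Among genes of resting and activated cells they were Ccr7 (-2.04), Il2ra (-1.71), Foxo1 (-0.99), Anxa2 (-1.75), Lgals1 (-1.59), Lgals3 (-4.76), Il2rb (-2.48), Cd38 (-2.83), Ltb (-1.11), Tnf (-0.92), Bcl2l1 (-2.03), Bcl2 (-0.76), Klf6 (-2.97), Ier2 (-1.34), Egr1 (-1.54), Nr4a1 (-3.75) and Mx1 (-1.16). Fyn (2.97), Cd5 (0.62), Etv5 (-0.89), Tpi1 (1.14), Aldoa (1.6), Gapdh (0.49), Gmfg (-1.29), Tns4 (-4.85) and H2-Ob (2.95) followed, and of cytotoxic genes Gzmb (-3.94), Nkg7 (-2.73), Cd8b1 (-0.88), Klrd1 (1.57) and Prf1 (1.86). The calls of Maf, Mx1, Slamf6, Cd8b1 and Gapdh held in 10, 8, 10, 11 and 13 of 23 alternatives. Of macrophage and B cell genes there were C1qb (-3.11), C1qc (-3.21), Csf1r (-3.93), Slc40a1 (-4.19), Itgam (2.46), Cd74 (-2.33), H2-Ab1 (-2.08) and Cd22 (-2.77). Some of these genes were near 0 in every non-TFH library, such as Ascl2 (at most 0.0495 FPKM), Cd22 (0.375) and Cd38 (0.658). Their values mostly give the change in TFH cells, since a change at such levels could hardly be seen. Il4 stood at 3.26 FPKM or less in non-TFH cells, where the scale understates its change.

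Macrophage markers fell in TFH and rose in non-TFH cells labelled KO, with an interaction. None of these calls held with an estimated correlation (adjusted p = 0.21, 0.28 and 0.069). The scaling of the values is excluded as the whole cause of the fall, since the list's median was at most -2.09 over the values as deposited and quantile normalization. RNA of macrophages in the TFH sort may contribute. Within genotypes the 14 members deviated together (mean correlation 0.48, percentile 100 of 1000 random lists). Genes regulated together in the sorted cells would deviate together as well, so this correlation cannot tell the origin of the RNA. C1qb stood at 293 and Csf1r at 152 FPKM in WT TFH cells. A gate on CD4 would remove cells without it that were sorted singly. The purity of the sort was not examined here, so the gate does not exclude RNA of macrophages. Of the 18 tested members 1 is in another list, and 14 were at 1 FPKM or more in WT non-TFH cells. Itgam, Lyz1 and Lyz2 rose, with 1.07 as the lowest log2 change, but they were picked because they rose, so this decides nothing. A response of the sorted cells to genotype stays open.

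Ets1 was not lower in KO libraries. Libraries swapped singly between WT and KO are excluded by the splits, of which the highest other gave 0.3% of the labelled count, but this test cannot see whole groups exchanged. Transcripts that keep undeleted exons cannot be told apart from an intact gene, at -0.03 log2 in non-TFH cells, since no value per exon was used here.

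The change of Treg genes differed between the cell types (median interaction -1.76). The list's median was -0.03 in TFH cells, where camera did not call it, and 0.91 in non-TFH cells. With the number of unnamed loci, a measure of background reads, as a covariate the median was -1.98. That number does not overlap between WT (12338 to 25171) and KO TFH libraries (7855 to 10233). The covariate is thus tied to genotype in TFH cells and cannot exclude background reads. Sex of the mice cannot be told apart from genotype and cell type: without WT TFH replicate 1, which had high Y-linked genes, the median was -1.88, but the libraries left still differ in Ddx3y between genotypes in TFH cells and between cell types, so the planned bound decides nothing. A different mix of cells in the sorts stays open, as does an effect of genotype on the genes themselves.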

How the results depend on the processing

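The covariates were chosen after the data were seen. Results, called or not, kept their direction and side of the threshold in 16359 comparisons of named genes with their alternatives, weakened in 471, strengthened in 54 and reversed in 1; for gene lists these were 3045, 86, 77 and 2. Unless stated the cause was not tested. Genes called in TFH cells numbered 2173 with the compared groups alone, 2237 with array weights, 1725 with unnamed loci as a covariate and 394 with Ddx3y, and limma called 0 with B cell and 0 with macrophage markers as covariates (961 and 843 at an unadjusted p under 0.05), each fitted to the 6 libraries alone. In non-TFH cells they numbered 3890 and 4167 with the first pair of these, and with a replicate block 3255 genes were called in TFH cells. Levels of Ddx3y and of B cell and macrophage markers differ between WT and KO TFH libraries, as does the number of unnamed loci. Calls lost with these covariates therefore do not decide a cause. Leaving out each library gave 2919 to 3353 in TFH cells, 1687 to 2457 in non-TFH cells and 1498 to 2103 for the interaction.

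Ets1 in TFH cells was 0.17 with quantile normalization and 0.37 with the compared groups alone, both uncalled, and 0.27 to 0.46 without single libraries; in non-TFH cells it was -0.05 to 0.01. Of 125 list tests 63 were called, against 15 with an estimated correlation, 104 with fry, 122 with fry for mixed directions and 58 to 66 without single libraries. The TFH signature moved by 0.384 when defined in KO mice and by -0.177, the reverse, with a 4-fold threshold. The correlation of the effects was 0.33 with the filter at 5 FPKM and 0.29 to 0.31 without single libraries. Uncalled results that reversed were the interactions of cell cycle genes (0.33) and Thy1 (0.67) with a pseudocount of 5, and the direction of cytotoxic markers between cell types of KO mice, which fry called upward (adjusted p = 0.02) at an unchanged median of -0.26. The count tool alternative was not run, since the tables hold no counts. Depth was estimated and not measured, and what it limits at low levels was not tested.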

Other observations

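The test of a lower share of Foxp3-expressing cells was chosen after the result was seen. Xist, of the inactive X chromosome, and the Y-linked Ddx3y were compared as deposited. KO TFH libraries had Xist at 26.1, 18.95 and 16.8 FPKM and Ddx3y listed at 0. WT TFH replicate 1 had Xist listed at 0 and Ddx3y at 38.03, and replicates 2 and 3 had Xist at 17.75 and 15.42 and Ddx3y at 2.46 and 5.95. Ddx3y stood at 58.23 and 45.78 FPKM in WT non-TFH replicates 2 and 3, and at 38.19, 41.3 and 36.75 in the KO non-TFH libraries. Xist stood at 1.55 and 0.14 FPKM in those WT libraries and at 18.04, 0.3 and 0.08 in the KO non-TFH libraries, so that KO non-TFH replicate 1 had signals of both genes. WT non-TFH replicate 1 had no value for either.

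Some genes were listed at 0 in a whole group and high in others. Of 534 tested features listed at 0 in a library and at 10 FPKM or more in another, 153 were called in TFH and 86 in non-TFH cells for KO against WT. Tmem243 was listed at 0 in each WT non-TFH library and at 94, 87.4 and 81.4 FPKM in the KO non-TFH libraries.

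The fall of Foxp3 in KO TFH cells may come from a lower share of Foxp3-expressing cells in the sort. In the test of a lower share of Foxp3-expressing cells in the KO TFH sort, 3 of 16 other Treg members had a log2 change of -1.29 or lower, which is the bound set from the change of Foxp3. Members that other TFH cells also express can hide a fall, so a lower share cannot be told apart from lower Foxp3 in the same cells.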
